A study of Homo sapiens with 3 samples.

How the data were processed

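Total RNA of 3 cultures of the human lung cancer line NCI-H1299 was measured on 1-colour expression arrays, 1 array each for mock, miR-34a and ghR-34a. Per the labels' protocols, RNA was extracted with ISOGEN, and biotinylated cRNA was made from 250 ng of total RNA. The authors deposited 1 table of linear probe set intensity for 54675 probe sets per array. Per the submitters' processing notes these came from Affymetrix Expression Console, with version and settings not given in the sources used here. The deposited intensity values had the same 2% trimmed mean, 500.1, on all 3 arrays, so they carry a common scaling of each array. They ranged from 0.053 to 49040. No detection calls came with the values used here, so it is not known which low signals are above background. Whatever background correction was used upstream affects these low values most.

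From these values log2(signal + 32) was computed, with no further scaling between arrays. The pseudocount damps differences between low signals. The 62 control probe sets were set aside. Probe sets were named from the platform annotation: 41097 had a single gene symbol, 1801 had several and were not used, and 11721 were unnamed here. Of the single-gene probe sets, 41043 matched a RefSeq gene of the current human assembly by its Entrez identifier and 0 symbols needed an update. For each of 19775 genes the probe set with the highest mean over the 3 arrays was used. A gene was kept where that mean was at or above the median of all probe sets, a signal of about 68.6, which left 11917 genes. Genome coordinates are not given, because the files name no genome build, and no genome or transcript sequence was used. The planned analysis of miR-34a seed sites in 3′ untranslated regions was therefore not run.

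The labels give 1 array per condition, so no test between conditions was possible. Genes were counted by a rule of size, a log2 difference of at least 1. Of 24 gene lists, 21 had at least 5 kept members. Their median log2 difference was placed among the medians of 10000 random lists of the same size, drawn from 10 bins of mean signal. A list was said to stand apart at or below the 2.5 or at or above the 97.5 percentile. This describes these arrays and is not a test of the conditions. The lists, the size rule, the filter, the alternatives and the genes to be named were fixed before the data were examined. The lists were written from general knowledge, and some share members. The genes named were the 10 with the largest difference each way against mock, the 5 with the largest difference each way between the transfectants, up to 4 members of each list that stood apart or was a main list (reported targets and both cell cycle lists), 15 well-known miR-34a targets, ACTB and GAPDH.

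Both differences from mock use the same mock array. Unchanged arrays sharing 1 mock array were therefore simulated 100 times. Their noise was drawn by signal bin from the difference between the transfectant arrays divided by the square root of 2, which is too large where the RNAs truly differ. Combining independent draws also thins the largest differences, so simulated counts at 2-fold may be too small. The size rule was tested on simulated data for miR-34a against mock, with 200 of 11917 genes changed. It recovered 50.1% of 2-fold, 97.5% of 3-fold and 99.8% of 4-fold changes, with 58.0 to 60.2 false calls on average. These folds were set on the log2 scale after the pseudocount was added. The same fold of the signal itself gives a smaller difference there, so fewer would be recovered among genes of low signal. The 50.1% follows largely from the design, because a 2-fold change lies on the cutoff of the size rule. Of 200 simulated lists of 50 unchanged genes, with noise drawn independently for each gene, 3.5% stood apart, and 100.0% did when shifted by -0.3. Probe sets other than the one used served as a check within an array. Among 6026 genes with a second probe set above the filter, the log2 differences of both correlated across genes at r = 0.57 for miR-34a and 0.48 for ghR-34a against mock. Of 58 genes at least 2-fold lower with miR-34a that had a second probe set, 54 were lower there too, and so were 18 of 19 for ghR-34a. Between the transfectants the correlation was weaker, at r = 0.36. There 6 of 8 lower genes were lower in the second probe set (median -0.20), and 16 of 16 higher genes were higher (median 0.51).

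The alternatives tried were no filter and a stricter filter, other size rules, median centring, quantile normalization, the mean of all probe sets of a gene, leaving out probe sets whose identifiers mark possible cross-reaction (_s_at and _x_at), pseudocounts of 1 and 100, and random lists not matched on signal. Their effect is given in the closing section. Below, values without cross-reacting probe sets leave out all _s_at and _x_at probe sets, whether or not these do cross-react. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.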

Results

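The study asked which mRNAs regulated by the microRNA miR-34a are lost from the cell, as opposed to being blocked in translation, by profiling total RNA from transfected cells. NCI-H1299 is a human non-small cell lung carcinoma line that lacks functional p53, a transcription factor that normally activates the MIR34A gene. There were 3 arrays, 1 each from mock cells, cells transfected with miR-34a and cells transfected with ghR-34a, a second RNA that the labels describe only by this name. Both RNAs were given at 25 nM for 48 hours, and 250 ng of total RNA was labelled for each array. What the mock cells received is not described further. No array came from cells given an unrelated RNA. Differences from mock, also those of the cell cycle lists, may therefore include a response to any transfected RNA. They may also include differences between single cultures. Each array measured 54675 probe sets. The median signal was 70.6 in the mock array, 74.98 in the miR-34a array and 69.2 in the ghR-34a array. With 1 array per condition, no spread between replicates could be estimated and no gene could be tested. The values below therefore describe these 3 arrays, carry no SD or p-value, and are compared by size. The number of arrays limits their precision. The small RNAs themselves were not measured here.

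A total of 11917 genes passed the signal filter. A gene was counted as lower or higher at a log2 difference of at least 1, which is 2-fold, after 32 was added to each signal. All log2 differences and folds below are on that scale, which understates the change of genes with low signal. Spike-in control probe sets gave a measure of the part of the technical spread that arises after these controls were added. Across 42 of them, the SD of the log2 difference from mock was 0.13 for miR-34a and 0.16 for ghR-34a. GAPDH differed from mock by -0.022 and -0.11 in the miR-34a and ghR-34a arrays, and ACTB by 0.12 and 0.065. The ratio of 3′ to 5′ GAPDH control signal, a sign of RNA integrity, was 0.967 in mock, 0.924 in miR-34a and 0.932 in ghR-34a. The 3 control probe sets for 18S ribosomal RNA were lower than mock in both transfectant arrays, by log2 differences of -0.26 to -0.49 with miR-34a and -0.25 to -0.31 with ghR-34a.

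The first comparison asked how mRNA levels differed between miR-34a transfectants and mock cells. Reported miR-34a targets were lower as a group. FOSL1, a subunit of the AP-1 transcription factor, had the largest difference of all genes, with a signal of 6509 in mock and 1183 in miR-34a, a 5.38-fold lower level. MET, the receptor for hepatocyte growth factor, went from 3269 to 1072, 2.99-fold lower. AXL, another receptor tyrosine kinase, went from 20614 to 8306, 2.48-fold lower. TPD52, a tumour-associated vesicle trafficking protein, and RRAS, a Ras-related GTPase, were 3.15-fold and 2.99-fold lower. All 4 other probe sets of TPD52 above the filter were also lower, as were both others of MET and the single other of AXL. FOSL1 and RRAS have 1 probe set each.

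In the whole list of reported targets, written from general knowledge before the data were examined, 59 of 80 genes passed the filter. Of these, 54 were below mock in the miR-34a array, 15 were at least 2-fold lower, and 0 were at least 2-fold higher. The median log2 difference was -0.68, with quartiles of -1.005 and -0.31. It lay below the medians of all 10000 random lists matched on signal. Among cell cycle targets, CDK4 (log2 difference -1.04), CDK6 (-0.94), CCNE2 (-0.78) and E2F3 (-0.79), which drive passage from G1 into S phase, were all lower, and CCND1, which encodes cyclin D1, was at -0.37. The transcription factor LEF1 of the Wnt pathway was at -1.17 (-0.93 with a pseudocount of 100) and the deacetylase SIRT1 at -0.71. Several well-known targets were closer to mock. MYC was at -0.36, MDM4 at -0.21 and CD44 at -0.056. BCL2 was at -0.27, from a mock signal of only 94.1. The Notch receptor NOTCH1 and its ligand JAG1 were above mock, at 0.39 and 0.25. For CD44, 10 of 11 other probe sets above the filter had the opposite sign, and for MDM4 2 of 5 did.

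**Figure D1:**
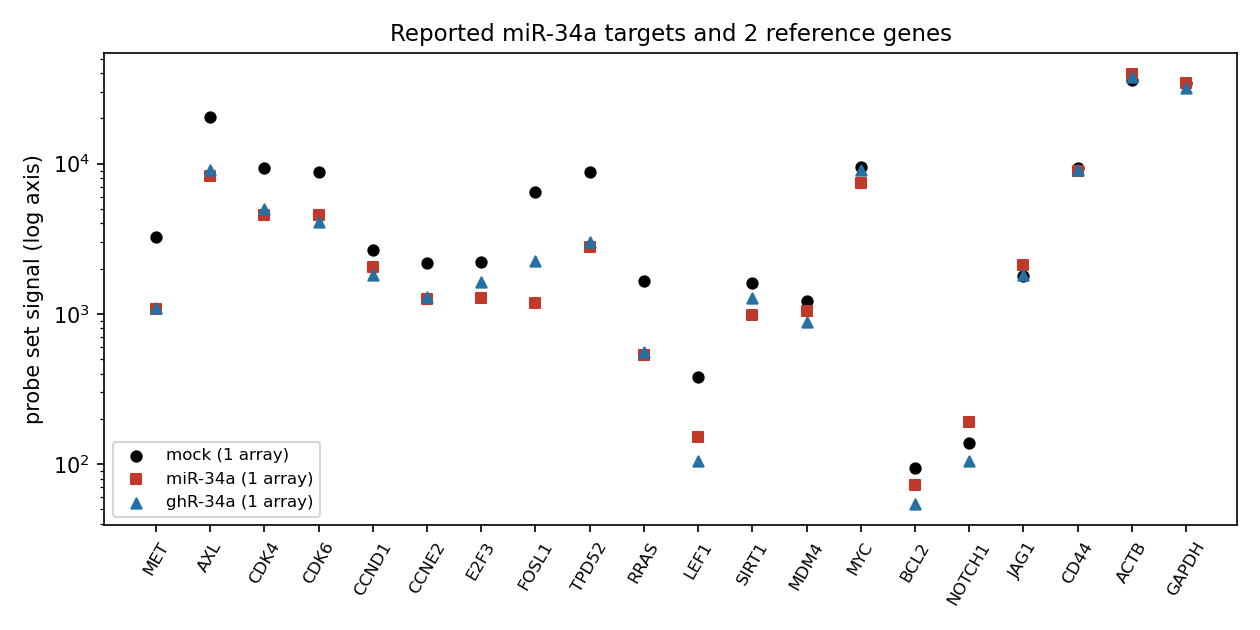
Probe set signal (log axis) of 18 reported miR-34a targets and the reference genes ACTB and GAPDH in the mock, miR-34a and ghR-34a arrays, 1 point per array. MET, AXL, TPD52 and RRAS lie at similar reduced levels in both transfectant arrays, FOSL1 is lower with miR-34a (1183) than with ghR-34a (2253), and CD44, ACTB and GAPDH stay close to mock.

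Cell cycle genes were lower as groups. Of 53 genes of G1/S progression and DNA replication, 52 were below mock in the miR-34a array and 8 were at least 2-fold lower, with a median of -0.63 (quartiles -0.82 and -0.49). GINS1 (-1.23) and GINS3 (-1.19), members of the GINS complex of the replicative helicase, TK1 (-1.15), which encodes thymidine kinase, and the transcription factor E2F2 (-1.09) had the largest differences, but E2F2 was short of 2-fold with averaged probe sets (-0.99) and with a pseudocount of 100 (-0.98). Of 61 genes of G2/M and mitosis, 56 were below mock but only 1, the condensin subunit NCAPH (-1.26), was at least 2-fold lower. The median was -0.38. CDCA8 (-0.92), FOXM1 (-0.87) and BIRC5 (-0.83) followed. Both medians were below those of all random lists. Genes of nucleolar function and biosynthesis known to respond to MYC had a median of -0.17 at percentile 0.14. In that list PAICS, an enzyme of purine synthesis, was at -0.86, RCL1 at -0.63, ODC1 at -0.54 and LDHA at -0.54, and 0 of 30 reached 2-fold.

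Interferon-stimulated genes were higher. Of 29 that passed the filter, 26 were above mock in the miR-34a array, and the median was 0.49 (quartiles 0.21 and 0.76), above all random lists. Only 2 were at least 2-fold higher. These were IRF9 (1.42), a subunit of the transcription factor complex that answers type I interferon, and IFI6 (1.21). IFIT1 was at 0.96 and IFIH1, a sensor of double-stranded RNA, at 0.89. Genes of lysosome and autophagy stood slightly above mock, with a median of 0.18 at percentile 99.8 and 0 of 36 at 2-fold. LIPA was at 0.75, MAP1LC3B at 0.45, ATG7 at 0.37 and GLA at 0.33. That list no longer stood apart when each gene's probe sets were averaged (median 0.10, percentile 92.8), or without cross-reacting probe sets (0.16, percentile 96.4). The receptor tyrosine kinase and MAPK list was at -0.12 (percentile 0.755), led by FOSL1, MET, RRAS and AXL, which are also in the target list. Its median was 0.022 when each gene's probe sets were averaged, and the list no longer stood apart without a filter (-0.081, percentile 2.75).

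Over all genes, 136 were at least 2-fold lower and 145 at least 2-fold higher in the miR-34a array than in mock. Arrays simulated without any effect, with noise taken from the spread between the transfectant arrays, gave 31.1 lower and 31.9 higher genes on average. These simulated counts may be too small, since the transfectant arrays themselves differed by 2-fold in 41 genes one way and 39 the other. Besides FOSL1, TPD52 and RRAS, the 10 genes with the largest negative differences included ECHS1 (-2.05), a mitochondrial enzyme of fatty acid oxidation, and GPN1 (-1.80), a GTPase needed for nuclear import of RNA polymerase II. They also included TSEN15 (-1.64) of the tRNA splicing endonuclease, SPCS2 (-1.63) of the signal peptidase, the receptor UTS2R (-1.77) and the antisense transcripts KIF9-AS1 (-1.81) and HMMR-AS1 (-1.66). Of the 10 genes with the largest positive differences, 5 encode proteins of motile cilia or close relatives. DNAI4 had a signal of 337 with miR-34a and of only 41.5 in mock, and its 3 other probe sets above the filter were also higher, at a median of 1.28. DNAAF4, an assembly factor of axonemal dyneins, went from 213 to 962, 4.05-fold higher. DNAI7 (1.95), CFAP206 (1.82) and CFAP299 (1.72) were higher too, as were CCDC24 (2.11), TMEM191A (1.81), MIR1-1HG (1.81), CCDC157 (1.81) and XCL1 (1.79). Of these 10, only DNAAF4 and CFAP206 had mock signals above 68.6, the level of the filter, so the sizes for the other 8 are uncertain, as is that of KIF9-AS1, with a miR-34a signal of 20.1. With averaged probe sets SPCS2 (-0.78) and CCDC157 (0.52) were short of 2-fold. The XCL1 probe set is of a kind that can cross-react with similar transcripts.

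Lists that did not stand apart in the miR-34a array included p53 target genes (median 0.024, percentile 41.6), apoptosis genes (-0.016, percentile 23.0), NF-kappaB and inflammatory genes (0.15, percentile 83.6), Notch pathway genes (0.14, percentile 86.1), Wnt pathway genes (0.034, percentile 45.6) and genes of epithelial-mesenchymal transition (0.073, percentile 73.0). RNA interference machinery (-0.11, percentile 3.67), cholesterol synthesis (-0.13, percentile 3.65) and the senescence-associated list (0.15, percentile 91.6) did not either, although cholesterol synthesis did without a filter (-0.15, percentile 1.89) and the senescence-associated list did with averaged probe sets (0.21, percentile 98.1). Ribosomal proteins (0.020), oxidative phosphorylation (0.032), stress response genes (0.015), hypoxia and glycolysis genes (0.044) and the reference genes (-0.024) had medians near 0. Markers of other cell types were mostly below the filter. Only 3 of 16 measured leukocyte markers, 4 of 18 fibroblast and endothelial markers and 3 of 16 lung epithelial and neuroendocrine markers passed the filter. Over 3 comparisons, 63 list medians were ranked. Of these, 19 stood apart, where lists of genes that vary independently would give 3.15 on average. Genes of a list may vary together, some lists share members, and the 3 comparisons use the same arrays. The number to be met without any effect may therefore be larger than 3.15.

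**Figure D2:**
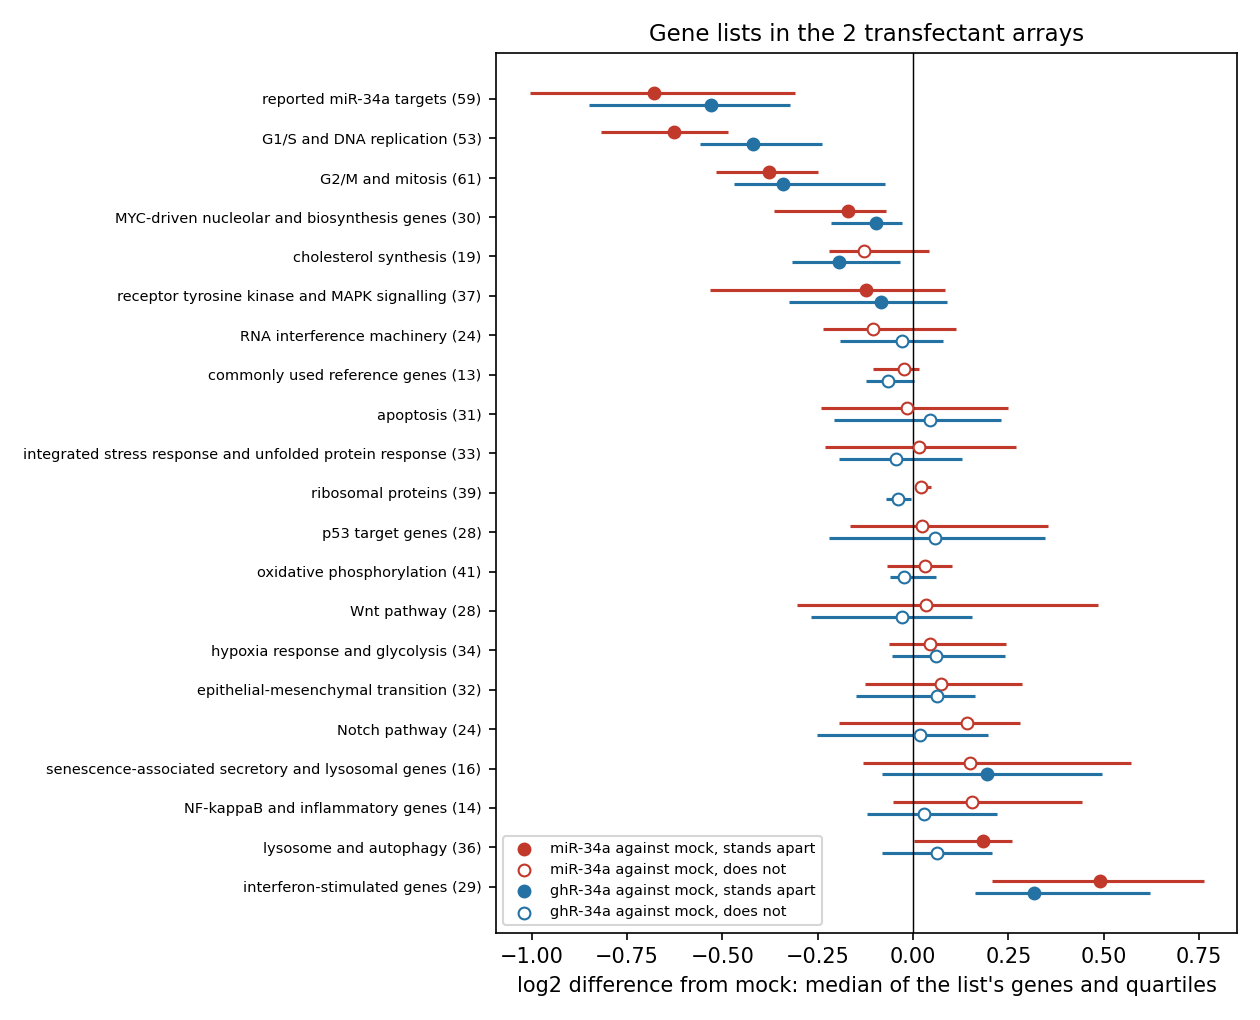
Median log2 difference from mock of each gene list (point) with its quartiles (line), for the miR-34a array (red) and the ghR-34a array (blue), with the number of genes in brackets. Filled points stand apart from random lists matched on signal. Reported miR-34a targets have medians of -0.68 and -0.53, and interferon-stimulated genes have medians of 0.49 and 0.32.

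The second comparison asked the same of ghR-34a. The reported miR-34a targets were again lower as a group. MET (signal 1101, 2.92-fold lower than mock), TPD52 (3008, 2.92-fold lower), FOSL1 (2253, 2.86-fold lower), LEF1 (105, 3.03-fold lower) and AXL (9045, 2.27-fold lower) were all at least 2-fold lower. Of the 59 targets that passed the filter, 56 were below mock, 11 were at least 2-fold lower and 0 at least 2-fold higher. The median was -0.53 (quartiles -0.85 and -0.32), below all random lists. CDK6 was at -1.08 (-0.99 with averaged probe sets), CDK4 at -0.90, CCNE2 at -0.74, CCND1 at -0.54, E2F3 at -0.44 and SIRT1 at -0.34. MYC (-0.075), CD44 (-0.034) and JAG1 (0.029) were near mock. MDM4 was at -0.44, NOTCH1 at -0.31 and BCL2 at -0.54, the last from signals of 94.1 and 54.6.

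Of the genes of G1/S and DNA replication, 51 of 53 were below mock in the ghR-34a array, with a median of -0.42 (quartiles -0.56 and -0.24). GINS1 (-1.42) and MCM5 (-1.07), part of the helicase that unwinds replication origins, were at least 2-fold lower. GINS3 was at -0.999 and TK1 at -0.96, just short of 2-fold, which both passed with averaged probe sets (-1.23 and -1.17). Of the G2/M and mitosis genes, 51 of 61 were below mock, none by 2-fold, with a median of -0.34. SPC25 (-0.83), NCAPH (-0.81), FOXM1 (-0.71) and PIMREG (-0.66) had the largest differences. Both medians were below those of all random lists. Interferon-stimulated genes were above mock in 27 of 29 cases, with a median of 0.32 (quartiles 0.16 and 0.62), above all random lists. IFIT1 (1.09) and DDX60 (1.05) were at least 2-fold higher, and IFI6 (0.83) and OASL (0.83) followed. With a pseudocount of 100 both of the first were short of 2-fold (0.99 and 0.86), and with a pseudocount of 1 OASL was at 1.09.

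Smaller shifts were seen in 4 other lists. Cholesterol synthesis genes had a median of -0.19 at percentile 0.12, with SREBF2 (-0.66), the transcription factor that controls the pathway, and the enzymes HMGCS1 (-0.56), DHCR7 (-0.56) and ACAT2 (-0.35). MYC-responsive genes had a median of -0.098 at percentile 0.45, with PAICS at -0.48, RCL1 and RRP9 at -0.35 and TERT at -0.34. The last had a mock signal of only 88.0. That list no longer stood apart with random lists not matched on signal (percentile 2.82) or without cross-reacting probe sets (-0.098, percentile 2.66). Receptor tyrosine kinase and MAPK genes had a median of -0.083 at percentile 1.86. This was 0.034 when probe sets were averaged, and did not stand apart with unmatched random lists (percentile 3.35) or without cross-reacting probe sets (-0.057, percentile 9.72). The senescence-associated list had a median of 0.19 at percentile 99.6. The collagenase MMP1 (1.37), the secreted glycoprotein STC1 (1.20), MMP10 (1.11) and the protease PLAU (0.54) led it, with 3 of 16 genes at 2-fold, of which MMP10 was at 0.75 with a pseudocount of 100. It did not stand apart with averaged probe sets (0.10, percentile 92.7) or without cross-reacting ones (0.20, percentile 96.5). Lysosome and autophagy genes (0.062, percentile 83.8), p53 targets (0.057, percentile 79.2) and apoptosis genes (0.044, percentile 71.8) did not stand apart, although p53 targets did without cross-reacting probe sets (0.16, percentile 97.9). Neither did NF-kappaB, Notch, Wnt, epithelial-mesenchymal transition, RNA interference, stress response, hypoxia, ribosomal, oxidative phosphorylation and reference genes, whose medians lay between -0.065 and 0.063.

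Over all genes, 68 were at least 2-fold lower and 54 at least 2-fold higher in the ghR-34a array. Simulated means for unchanged arrays were 31.1 and 31.9. These may be too small, since the transfectant arrays themselves differed by 2-fold in 41 genes one way and 39 the other. The largest negative difference from mock was in FGD2 (-2.32), an activator of the GTPase CDC42. Its other 2 probe sets above the filter, however, had a median of -0.16 and differed in sign. EXOC3L1 (-2.11), CYP3A4 (-2.07), SLC38A2-AS1 (-1.94), CACNG4 (-1.75) and PRRX2 (-1.67) followed, and none of these 5 had a second probe set above the filter. The ghR-34a signals of FGD2 (56.1), EXOC3L1 (11.6), CYP3A4 (30.7), SLC38A2-AS1 (26.6) and PRRX2 (22.5) were below the filter, so the sizes and order of these differences are uncertain. FGD2 was at -0.48 without cross-reacting probe sets. NUP210, a nuclear pore protein, was at -1.58, and all 4 of its other probe sets were lower. The largest positive differences were in DNAI4 (2.21), CCDC157 (2.04), PACS1 (1.68), CCDC24 (1.48), OSCP1 (1.48), DNAAF4 (1.45), the SUMO protease SENP7 (1.43), TMEM191A (1.37), MMP1 (1.37) and DYNC2LI1 (1.36). The mock signals of DNAI4, CCDC157, CCDC24 and TMEM191A were below the filter, with the same uncertainty. With averaged probe sets DNAI4 (0.97), CCDC157 (0.94), PACS1 (0.73), SENP7 (0.84), NUP210 (-0.93) and CACNG4 (-0.70) were short of 2-fold, and the second probe set of SENP7 was at 0.24. With a pseudocount of 100 CCDC24 (0.89), TMEM191A (0.80) and PRRX2 (-0.98) were. DYNC2LI1 is a subunit of the dynein that moves cargo within cilia. Its signal went from 513 to 1366, and its 3 other probe sets were higher as well.

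The third comparison set ghR-34a against miR-34a at the same dose and time. The reported targets were at similar levels with both RNAs. Their median difference, ghR-34a minus miR-34a, was 0.043, with quartiles of -0.090 and 0.20, at percentile 96.2, which did not stand apart. It did stand apart when each gene's probe sets were averaged (0.082, percentile 99.9) and against unmatched random lists (percentile 97.6). MET differed by 0.036, RRAS by 0.065, TPD52 by 0.11, AXL by 0.12, CDK4 by 0.13 and CDK6 by -0.15. Targets with a higher level in the ghR-34a array included FOSL1 (0.91), ACSL4 (0.46), PEA15 (0.38) and SIRT1 (0.36). None of the 59 differed by 2-fold. The cell cycle lists differed more evenly. In 51 of 53 genes of G1/S and DNA replication the signal was higher with ghR-34a than with miR-34a, with a median of 0.21 above all random lists. HELLS (0.61), CCNE1 (0.60), ORC1 (0.54) and E2F2 (0.54) differed most. The other E2F2 probe set above the filter was at only 0.025, those of HELLS were at 0.23 to 0.45, and CCNE1 and ORC1 have no other. CCNE1, which encodes cyclin E1, was at mock level with miR-34a (0.033) and above it with ghR-34a (0.63).

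For G2/M and mitosis the median was 0.12, again above all random lists, with CENPI (0.53), ECT2 (0.46), NCAPH (0.45) and BUB1B (0.44) at the top. The other probe set above the filter was at -0.11 for CENPI and 0.24 for ECT2, and NCAPH and BUB1B have 1 probe set each. Without cross-reacting probe sets it was 0.061 at percentile 95.5. MYC-responsive genes had a median of 0.13 at percentile 99.97, with PAICS (0.39), NCL (0.38), ODC1 (0.36) and PES1 (0.35). This was 0.010 at percentile 72.6 with averaged probe sets and 0.077 at percentile 94.4 without cross-reacting ones. The senescence-associated list had a median of 0.12 at percentile 98.7, led by HMGA1 (0.41), TIMP2 (0.38), IGFBP3 (0.29) and CDKN1A (0.27). It was at percentile 90.3 without cross-reacting probe sets. Other probe sets above the filter were at -0.001 for HMGA1, a median of -0.011 for TIMP2 and 0.11 for IGFBP3, and CDKN1A has 1 probe set. With miR-34a and ghR-34a, IGFBP3 (-1.04 and -0.74) and CDKN1A (-0.39 and -0.12) were below mock, so they were less reduced with ghR-34a. Interferon-stimulated genes differed by a median of -0.11, which did not stand apart (percentile 14.6). Nor did genes of lysosome and autophagy (-0.090, percentile 2.68) or of receptor tyrosine kinase and MAPK signalling (0.062, percentile 97.4), but both lay close to the limits and passed them under 5 and 4 alternative settings.

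Over all genes, 41 were at least 2-fold lower and 39 at least 2-fold higher with ghR-34a than with miR-34a. Genes at least 2-fold lower made up 51.25% of these, and 40.8% after quantile normalization. The largest positive differences were in MYL10 (2.02), ECHS1 (3.89-fold), GPN1 (1.77), UTS2R (1.72) and NDFIP2 (1.52), an adaptor of NEDD4-type ubiquitin ligases. ECHS1 had signals of 6027 in mock, 1433 with miR-34a and 5668 with ghR-34a, and GPN1 had 3217, 902 and 3163. The largest negative differences were in BICDL1 (-1.87), TMPRSS6 (-1.81), PRPF40B (-1.68), EXOC3L1 (-1.67) and MEN1 (-1.63). MYL10, BICDL1, TMPRSS6, PRPF40B and EXOC3L1 each had 1 of these 2 signals below the filter, and with a pseudocount of 100 EXOC3L1 was at -0.89. MEN1 encodes the tumour suppressor menin, with signals of 1011 in mock, 1241 with miR-34a and 379 with ghR-34a from its only probe set.

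Of the genes that differed from mock by at least 2-fold, 28 were lower in both transfectant arrays and 37 higher in both, and 0 differed in opposite directions. Independent lists of these sizes would share 0.776 and 0.657 genes. Unchanged arrays that share 1 mock array shared 6.68 and 6.85 genes on average in simulation. These simulated numbers may be too small, because the simulation thins the largest differences. The log2 differences of all genes correlated with Pearson r = 0.68 and Spearman rho = 0.65 across genes, which are not independent replicates. The simulated r, which comes only from the shared mock array, was 0.50. The covariance was 0.085, against 0.042 in simulation, a difference of 0.043. With a single mock array the controls could not be split, so part or all of the excess may come from that array, if it is noisier than the others. Of 136 genes lower with miR-34a, 125 were also below mock with ghR-34a, at a median of -0.72 against -1.15. Of 145 higher with miR-34a, 144 were above mock with ghR-34a, at 0.78 against 1.18. Of 68 genes lower with ghR-34a, 62 were also below mock with miR-34a, at -0.93 against -1.20. Of the 54 higher with ghR-34a, 53 were above mock with miR-34a, at 1.25 against 1.13. Unchanged arrays sharing 1 mock array give high shares as well. In simulation 89.3% of lower genes were also below mock in the other array, at a median of -0.59, and 89.1% of higher genes were above it, at 0.57. The observed shares were 91.9% and 91.2% for the lower genes of miR-34a and ghR-34a, and 99.3% and 98.1% for the higher genes.

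**Figure D3:**
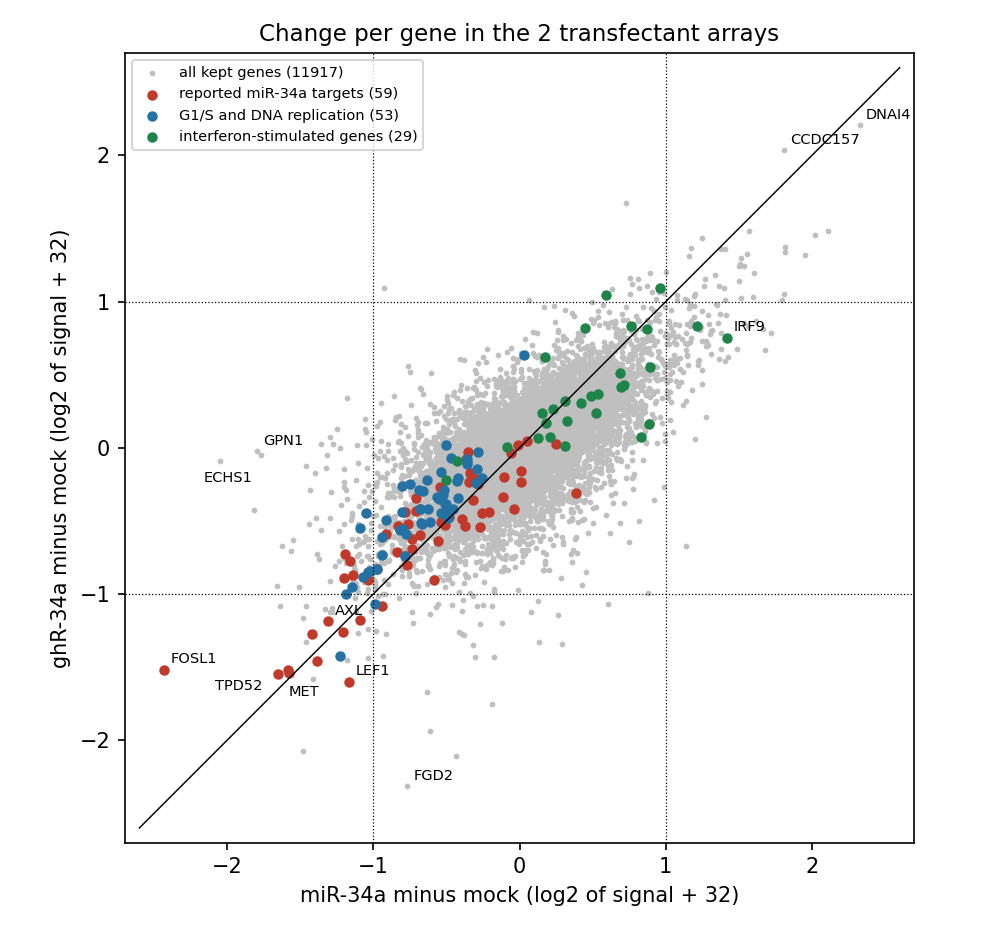
Log2 difference from mock per gene in the miR-34a array (x axis) and the ghR-34a array (y axis), for 11917 genes in grey with 3 gene lists in colour. Dotted lines mark 2-fold and the solid line equality. Reported targets such as MET and TPD52 lie near the line, while ECHS1 and GPN1 are lower only on the x axis. Both axes share the mock array, which alone gives r = 0.50 in a simulation with the same noise on all 3 arrays.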

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

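The search for an array of cells given an unrelated RNA, the second probe sets of the interferon genes on the ghR-34a array and those of the genes lower with 1 RNA alone on the other array were tests chosen only after the result was seen, and the requirement that a bootstrap interval clear the value allowed by probe set error was added after the medians of the second probe sets were seen. The patterns themselves were noticed in these data, and IFNB1, CXCL10 and CCL5 were looked up afterwards. All bootstrap intervals below resample genes. They describe the spread between genes within these arrays and not the spread between cultures.

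Among the named genes, 4 differed from mock in opposite directions in the transfectant arrays, by more than 3 times the SD of the spike-in probe sets. That SD holds technical noise alone, and signals as low as these are noisier, so passing it does not show a real opposite difference. The difference was not tested, since each condition has 1 array. MYL10 was at -0.93 with miR-34a and 1.09 with ghR-34a, a difference of 2.02. BICDL1 was at 0.88 and -0.99 (-1.87), TMPRSS6 at 1.14 and -0.67 (-1.81), and PRPF40B at 0.61 and -1.07 (-1.68). None of these has a second probe set above the filter, and all have mock signals of at most 101. With a pseudocount of 100 the differences were 1.22 for MYL10, -1.13 for BICDL1, -1.18 for TMPRSS6 and -1.04 for PRPF40B, and none of the 4 reached 2-fold against mock in either array. Outside the named genes, 3503 unnamed probe sets passed the filter, of which 2 were at least 2-fold lower and 3 at least 2-fold higher in both transfectant arrays.

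In the miR-34a array alone, 30 genes were at least 2-fold lower while ghR-34a lay less than 0.3 below mock, among them ECHS1, GPN1, UTS2R and NDFIP2, with a median mock signal of 1046. The reverse held for 13 genes, among them MEN1, CACNG4 and PRPF40B, with a median mock signal of 143. Error of single probe sets was argued against for the first set: 13 of its genes have a second probe set above the filter, 12 of these were lower, and their median was -0.55 (bootstrap interval -0.79 to -0.25), while with ghR-34a the same probe sets had a median of 0.014 and all 13 lay less than 0.3 below mock. NDFIP2 is among these, but was at -0.56 when all its probe sets were averaged, and ECHS1, GPN1 and UTS2R have 1 probe set each and stay unchecked. For the second set only 2 genes have a second probe set (median -0.75), too few to decide. Whether the first set may reflect sequences or strands that only the miR-34a reagent contains, or a difference between 2 single cultures, stays open and was not tested here.

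Interferon-stimulated genes were higher in both transfectant arrays. Error of single probe sets was not excluded for the miR-34a array: 8 of 10 second probe sets were higher, with a median of 0.30 that met the bound of 0.3 set beforehand, but the added bootstrap interval of 0.063 to 0.50 reaches the 0.1 that such error allows. For the ghR-34a array 9 of 10 were higher with a median of 0.24 (0.13 to 0.66). That met a bound of 0.2 first written for this added test but not the 0.3 used for miR-34a, to which it was then held, so it stays open too. A response to any transfected RNA cannot be told apart from an effect of the miR-34a sequence, because 0 arrays came from cells given an unrelated RNA. An effect of miR-34a itself also stays open, and signals for IFNB1 (1.52 in mock, 25.2 and 18.5 in the transfectants), CXCL10 (68.2, 47.4 and 56.4) and CCL5 (11.2, 46.5 and 57.9) were below the filter and are not readable as changes.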

How the results depend on the processing

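With no replicates, no array could be left out. No paired analysis was possible because each condition has 1 array. The seed site analysis was not run for want of transcript sequences. Counts below are given as lower and higher for miR-34a against mock, ghR-34a against mock and ghR-34a against miR-34a, then genes shared by both transfectants (lower, higher) and the Pearson r between them. The reported counts are 136 and 145, 68 and 54, 41 and 39, then 28 and 37, with r = 0.68. Without a filter (19775 genes) they were 278 and 380, 228 and 215, 256 and 176, then 70 and 90, with r = 0.59. With the filter at the 75th percentile (7764 genes) they were 81 and 53, 28 and 19, 9 and 17, then 18 and 12, with r = 0.73. A size rule of 1.5-fold gave 633 and 794, 484 and 380, 390 and 267, then 221 and 265. A log2 rule of 2 gave 2 and 3, 3 and 2, 0 and 1, then 0 and 1. The mean of all probe sets gave 89 and 81, 42 and 29, 16 and 18, with 21 genes higher in both. A pseudocount of 1 gave 229 higher with miR-34a, 123 and 100 with ghR-34a, 94 lower with ghR-34a than with miR-34a, then 43 and 66 shared, with r = 0.67. A pseudocount of 100 gave 74 and 61, 33 and 19, 14 and 18, then 17 and 13, with r = 0.69. Without cross-reacting probe sets r was 0.67. Median centring and quantile normalization kept every count within 1.5 times, but with miR-34a they gave more lower than higher genes (159 and 120, and 149 and 129), while the main analysis had fewer lower than higher (136 and 145). Fewer genes tested, or a larger size or pseudocount, lower these counts by construction. The counts therefore depend on how genes of low signal are treated. The medians of the reported targets and of both cell cycle lists against mock stood apart on the lower side under all 9 planned settings, and, in an alternative chosen after seeing the data, without members of the other main lists. Between the RNAs, the reported targets came to stand apart with unmatched random lists (0.043, percentile 97.6) and with averaged probe sets (0.082). So did lysosome and autophagy under 5 settings (-0.13 to -0.088), receptor tyrosine kinase and MAPK signalling under 4 (0.062 to 0.078), epithelial-mesenchymal transition with averaged probe sets (-0.175, percentile 0.20) and the stress response list without a filter (-0.10, percentile 2.45). The G2/M list no longer stood apart without cross-reacting probe sets (0.061). The receptor tyrosine kinase and MAPK list turned from negative to 0.022 (miR-34a) and 0.034 (ghR-34a) with averaged probe sets; the cause was not tested. Of 576 alternative list medians, 545 stood apart or not as before, 13 ceased to stand apart with the same sign and 16 came to. The other 2, of receptor tyrosine kinase and MAPK genes with averaged probe sets, changed sign and ceased to stand apart (percentiles 43.4 and 74.5). In 34 of the 545 the median, which did not stand apart, had the other sign or was 0. Of 2214 alternative values of named genes, 2151 kept their side of the 2-fold rule, 43 dropped below it, 20 passed it and 0 reversed a 2-fold difference. Of the 43, 21 dropped with a pseudocount of 100 (CCDC24, DDX60, DNAI7, E2F2, EXOC3L1, IFIT1, IGFBP3, KIF9-AS1, LEF1, MIR1-1HG, MMP10, MYL10, PRPF40B, PRRX2, SLC38A2-AS1, STC1, TMEM191A, TMPRSS6 and XCL1) and 17 with averaged probe sets (ACSL4, CACNG4, CCDC157, CDK6, DNAI4, E2F2, HELLS, NDFIP2, NUP210, PACS1, SENP7, SPCS2 and STC1), some in more than 1 comparison. The others were FGD2 without cross-reacting probe sets, STC1 and XCL1 with median centring and PRRX2 with quantile normalization. Those that passed it included 10 with a pseudocount of 1.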

Other observations

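The axonemal families, their alternative settings and the upstream genes were chosen only after the largest differences were seen, as were the test of second probe sets on the ghR-34a array and the split by mock signal, CFAP20DC and DNAAF3-AS1 were left out after the values of the families were seen, and the bootstrap interval was added after the medians of the second probe sets were seen. Genes of the ciliary axoneme, the microtubule core of motile cilia, were higher in both transfectant arrays. The pattern was noticed among the genes with the largest increases, so gene families were then chosen by symbol alone (CFAP, DNAAF, DNAH, DNAI, DNAL, DRC, ODAD and RSPH). Of 52 such genes above the filter, 42 were above mock with miR-34a and 41 with ghR-34a, with medians of 0.55 and 0.29, both above all 10000 matched random lists. With miR-34a 11 were at least 2-fold higher and 1, DNAH6 (-1.04), at least 2-fold lower. With ghR-34a 7 were higher and 0 lower. CFAP53 was at 1.41 and 1.36, CFAP69 at 1.08 and 1.05, CFAP263 at 1.08 and 1.01, RSPH3 at 1.07 and 0.76 and DNAAF9 at 1.15 and 0.64. Between the RNAs the median, ghR-34a minus miR-34a, was -0.19 at percentile 0.25, with 14 genes above 0, but it did not stand apart without a filter (-0.069, percentile 30.9) or with the stricter filter (-0.047, percentile 28.3). Of the members with high signal, CFAP20 (mock signal 4974) was at 0.036 and 0.040, CFAP251 (4415) at -0.082 and 0.11 and DNAAF5 (7034) at 0.27 and 0.35.

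Error of single probe sets was argued against only in part. The 19 second probe sets above the filter had a median of 0.66 with miR-34a (bootstrap interval over genes 0.39 to 0.77). With ghR-34a their median was 0.42 (0.24 to 0.58), and 16 were higher in each array. Their filter uses all 3 arrays, so it favours second probe sets that are higher in the transfectants. How far this raised their medians was not tested. Picking of genes by their rise stays open. The 47 members not already named had medians of 0.43 and 0.27, both at percentile 100, but 3 of these (CFAP53, CFAP69 and CFAP263) were at least 2-fold higher in both arrays, and the families were chosen after such genes were seen, so the bound written beforehand, which these values meet, was not a fair test. The filter, which uses all 3 arrays, also favours genes that are higher in the transfectants. In 9 members the mock signal was below it, with medians of 0.87 and 0.77, and the other 43 had medians of 0.32 and 0.27. Without a filter the medians of 93 members were 0.23 and 0.18 (percentiles 99.99 and 100), and the stricter filter left 22 members at 0.25 and 0.18 (percentiles 99.7 and 99.8). No biological explanation was tested, and an effect of the transfected RNAs and a peculiarity of the single mock array were not separated. Of genes known to act upstream, the regulators FOXJ1 (signals 36.9, 4.86 and 10.8) and GMNC (46.2, 6.37 and 43.6) were below the filter, RFX3 was at 0.59 and 0.67, RFX2 at -0.14 and -0.13, and CCP110, which restrains ciliogenesis, was not lower (0.36 and 0.13).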
